A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

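RNA-seq libraries from total RNA were made with a TruSeq RNA kit from 4 samples of Saccharomyces cerevisiae strain CRY, a MATa strain with 5 auxotrophic markers, per the labels, which do not state whether strand was kept. The groups are 2 control samples and 2 manganese-adapted samples, assigned from the adaptation status in the labels, with replicate numbers from the sample titles. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, control cells were grown for 18 h in rich medium holding an estimated 0.0036 mM manganese, and adapted cells for 120 h in the same medium with 2.5 mM manganese sulfate, both to the stationary stage. Culture time therefore differs with manganese in all samples, and no covariate can separate them.

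The analysis starts from 1 table of 7126 features deposited by the authors. Per the submitters' processing notes, cutadapt 1.8.1, TopHat2 2.0.13, Bowtie, HTSeq and edgeR were named with genome build sacCer3; their roles, the annotation, the counting mode and the strand setting are not given in the sources used here. The 4 columns of per-sample values are headed as counts in the file, but the deposited values are CPM, reads scaled by an effective library size. Each value lay within 0.001 reads of a whole multiple of the value of 1 read in its library (largest distance 3.7e-05 reads), so whole reads were recovered for every value. CPM recomputed with edgeR's TMM factors from the recovered reads differed from the deposited CPM by at most 3.9e-06. The deposited table also holds the authors' log2 fold change, p-value and false discovery rate per gene; the edgeR test behind them is not given in the sources used here. For 95.3% of genes that log2 fold change lay within 0.01 of the log2 ratio of mean CPM.

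The recovered reads summed to 14184276 and 13466475 in control replicates 1 and 2 and to 13739798 and 12307870 in manganese-adapted replicates 1 and 2, with scaling factors of 0.9961, 0.9886, 0.9868 and 1.0291. A floor of 3 reads corresponds to 0.212 to 0.237 CPM. These floors cover counting error only. Reads of rRNA and tRNA made up 0.0% of each library. Gene names, coordinates and coding lengths come from the R64 RefSeq annotation, to which 6047 features (84.9%) were matched by locus tag. That annotation is not the one the authors counted with, and coordinates are given only as R64 positions. For protein-coding genes with 1 coding exon all lengths are multiples of 3, so they are coding lengths without untranslated regions. For spliced genes the length is the span from start to end with introns, as in YDL012C (2 exons, 410 bp). Both are called coding lengths here. Without a stated strand setting, reads of antisense or overlapping genes and of near-identical paralogs cannot be assigned with certainty.

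A count test had been fixed for a table of counts and limma-trend for a table of CPM; the values are CPM, so limma-trend is the test reported. It was run in R 4.3.3 with limma 3.58.1 on log2(CPM + 1), for the 6296 features with at least 1 CPM in 2 or more samples, with no covariate and 2 residual degrees of freedom, and with Benjamini-Hochberg adjustment at 0.05. Fold changes are manganese-adapted minus control on the log2(CPM + 1) scale, which understates the change of low genes. Lists of genes (37, fixed before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, which left 35 lists, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. With an estimated correlation, camera tests on the 2 residual degrees of freedom, so a call lost there does not decide against a list. Errors are SDs over 2 samples for CPM and standard errors from limma for log2 fold changes.

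The genes named in the text follow a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 10 CPM and groups that do not overlap; the 5 most abundant genes changed at least 2-fold; every tested member of the lists of manganese transport, the plasma membrane proton ATPase, CYSTM-domain proteins, alpha-cell markers and auxotrophic markers; and up to 4 members of every other list, those with the largest change.

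The tests were checked on simulated reads for this comparison. Reads were drawn for the real genes from the control means, the real library sizes and the within-group dispersion, with 200 changed genes, 50 at each of 4 fold sizes. Of 6240 genes tested, limma-trend recovered 96% of the genes changed 1.5-fold and 100% of those changed 2-fold, 4-fold and 8-fold, with 13 false calls (6.2% of calls). Among 100 simulated lists of 30 genes, camera called all 10 that had been shifted 1.5-fold and 0 of the other 90. Simulated genes were drawn independently, so this does not check camera on lists whose members move together. The 200 changed genes were also far fewer than the 4313 of 6296 called in the real data, and rose and fell equally often. The recovery, false calls and list calls therefore hold only where most genes are unchanged. Cytosolic ribosomal proteins, for example, had an estimated correlation of 0.85 in the real data. Removal of a simulated coding length trend brought its rank correlation from 0.86 to 0.02 over 5722 genes.

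Alternatives fixed before the data were examined were DESeq2-type (RLE) size factors, no scaling factor, upper-quartile scaling, the DESeq2 1.42.0 Wald test and the edgeR 4.0.16 exact test on the recovered reads, other filters and pseudocounts (0.1 and 10), a stricter threshold of 0.01, a replicate block, exclusion of mitochondrially encoded and rRNA genes, and leaving out each sample. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads, a crossed pairing, removal of a smooth trend (loess, span 0.5) on coding length or GC content, leaving out overlapping genes, and fry with the replicate block. Members of the gene lists were matched by name or locus tag. Some results on gene lists added after the data were seen are not reported here. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.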

Results

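The transcriptome of manganese-adapted yeast was compared with that of control yeast in 4 RNA-seq libraries, 2 per group. The question addressed is how the transcriptome of yeast adapted to a toxic manganese concentration differs from that of cells grown without it. The control cells grew in rich medium at 0.0036 mM manganese for 18 h, and the adapted cells at 2.5 mM manganese for 120 h. The libraries held 12307870 to 14184276 recovered reads, and 574 of 7126 features had no reads in any library. Samples of a group correlated at 0.994 (control) and 0.996 (manganese-adapted), and samples of different groups at 0.917 to 0.931 (Pearson, across genes, which are not independent replicates). The first principal component held 94% of the variance and separated the groups. Replicates differed beyond sampling noise in both groups (chi-square per gene 23.36 in control and 10.71 in manganese-adapted), which does not tell separate cultures from separate preparations of 1 culture.

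On the log2(CPM + 1) scale, the 10 largest rises in the manganese-adapted libraries were led by HXT2 (YMR011W), a high-affinity glucose transporter, which went from 24.8 ± 1.64 to 791 ± 24.1 CPM (SD, n = 2 per group), a CPM ratio of 32-fold. ADH2 (YMR303C), the alcohol dehydrogenase that oxidises ethanol, rose from 56.3 ± 3.46 to 1563 ± 256 CPM. PMA2 (YPL036W), the minor isoform of the plasma membrane proton ATPase, rose from 27.1 ± 6.28 to 728 ± 116 CPM. MNC1 (YBR056W-A), a small protein with a CYSTM domain, rose from 2.39 ± 0.72 to 83.7 ± 0.23 CPM, a CPM ratio of 35-fold. YOR385W (log2 fold change 4.50), YNR064C (3.87), INO1 (3.80), which makes inositol-3-phosphate, and YPR145C-A (3.69) also rose. SPS100, a spore wall protein, rose from 26.5 ± 7.29 to 327 ± 35.3 CPM and overlaps an annotated antisense RNA. Also among the 10 was FDH2 (3.70), which is uncertain because it may share reads with its near-identical copy FDH1. These changes had adjusted p of at most 3.44e-08 (limma). Both manganese-adapted libraries lay above both controls for each, which the rule that picked them required. Of 6296 tested genes 4313 changed, 2118 higher and 2195 lower, and 975 changed at least 2-fold (521 higher, 454 lower). These changes are relative to the other genes of a library, with a median log2 fold change of -0.009. The near-even split is therefore largely set by the scaling, and a shift in total mRNA would not be seen.

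In R64, HXT2 lies on chromosome XIII at 288079 to 289704 (plus strand), ADH2 on XIII at 873291 to 874337 (minus strand), PMA2 on XVI at 482843 to 485686 (plus strand) and MNC1 on II at 351255 to 351455 (plus strand). Each is annotated as 1 protein-coding exon. The largest fall, DSE1 (YER124C), lies on V at 407342 to 409063 (minus strand), and DSE2 (YHR143W) lies on VIII at 385510 to 386487 (plus strand).

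**Figure D1:**
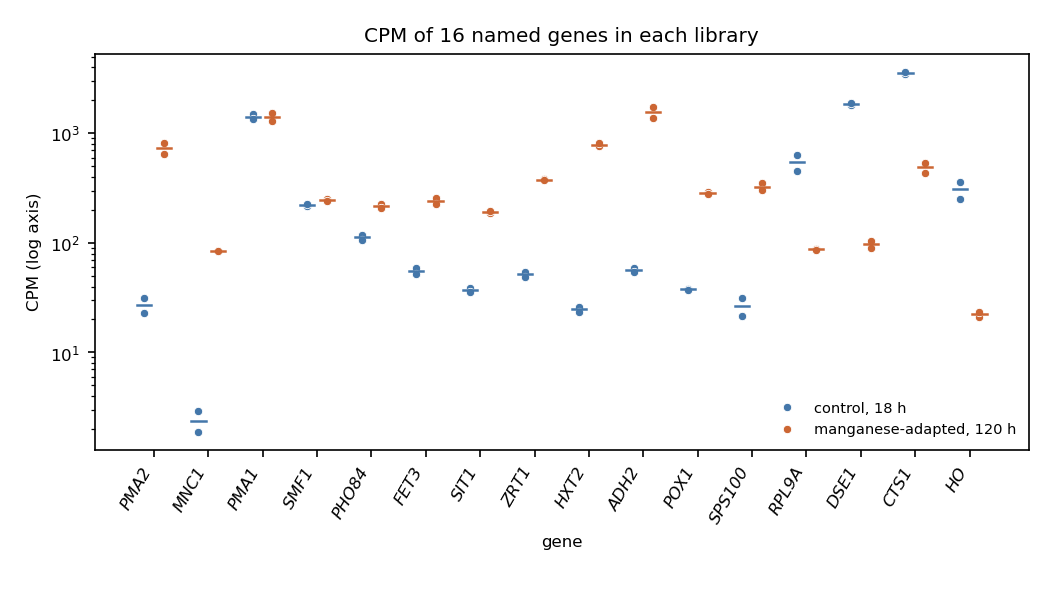
CPM of 16 named genes in each library on a log axis, with control in blue and manganese-adapted in orange, points for the 2 libraries of each group and bars for their means. PMA2 and MNC1 sit far above their control values in both manganese-adapted libraries, DSE1 and CTS1 far below theirs, and PMA1 overlaps.

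The 10 largest falls were led by DSE1 and DSE2. DSE1, a daughter cell-specific gene, fell from 1853 ± 56.8 to 97.0 ± 9.84 CPM (SD, n = 2), and DSE2, from 2202 ± 134 to 134 ± 11.3 CPM. SCW11, a cell wall glucanase-like protein, had a log2 fold change of -3.09, CTS1, the chitinase that separates daughter cells, of -2.86, and CWP1, a cell wall mannoprotein, of -2.74. HO, the endonuclease of mating-type switching, fell by 3.71 on the log2 scale and PSA1, which makes GDP-mannose, by 2.68. YNL277W-A fell by 3.24, YLR198C, which has no R64 locus tag, by 3.23, and RPL9A, a ribosomal protein with a near-identical copy and therefore uncertain, by 2.61. All 10 had adjusted p of at most 2.31e-07 (limma).

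The 5 most abundant genes changed at least 2-fold included 1 rise and 4 falls. SED1, a cell wall protein, rose from 6323 ± 303 to 16515 ± 1785 CPM (log2 fold change 1.382, limma adjusted p 0.00198). That call was lost without control replicate 1 or control replicate 2, though the log2 fold change stayed at 1.333 and 1.431. The falls were CCW12 (log2 fold change -1.88), EGO4 (-1.43), ZEO1 (-1.38) and HSP12 (-1.31), of which CCW12 and HSP12 encode a cell wall mannoprotein and a membrane-associated stress protein.

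Of 14 members of the list of manganese transport and homeostasis, 9 rose, 2 fell and 3 did not pass, and the list was not called (camera adjusted p 0.10). PHO84, a phosphate transporter that also carries manganese, rose (log2 fold change 0.95), as did SMF3 (0.76), TRE2 (0.64), SMF2 (0.63), CCC1 (0.60), PMR1 (0.38), TRE1 (0.31), YPK9 (0.29) and BSD2 (0.22). ATX2 (-0.84) and GDT1 (-0.76) fell. SMF1, the plasma membrane manganese transporter, was at 222 ± 6.77 and 247 ± 6.70 CPM (adjusted p 0.122), and SPF1 (-0.08) and MTM1 (0.05) did not pass. PHO84 overlaps an annotated antisense RNA over its whole coding region. With the coding length trend removed, PMR1 (0.05), TRE1 (0.00) and YPK9 (-0.09) no longer passed, SPF1 fell (-0.43), and TRE2 (0.33) and SMF2 (0.41) passed at a smaller size; the list's median went from 0.30 to 0.05. Without manganese-adapted replicate 1 the calls of TRE1 (adjusted p 0.0776), YPK9 (0.0683) and BSD2 (0.0863) were lost. Those of YPK9 (0.0579) and BSD2 (0.242) were lost without manganese-adapted replicate 2, and that of BSD2 without control replicate 2 (0.163), in DESeq2 (0.0581), in the edgeR exact test (0.0539) and with the replicate block (0.0677).

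Of 10 members of the proton ATPase list, 4 rose and 2 fell. PMA2 rose as above, together with HSP30 (0.62), AST2 (0.57) and AST1 (0.34), while PMP2 (-0.99) and PMP3 (-0.81) fell (-0.58 and -0.41 with the coding length trend removed). PMA1, the major isoform, was at 1423 ± 107 CPM in control and 1425 ± 168 CPM in manganese-adapted libraries (log2 fold change 0.00 ± 0.14 SE), and at -0.32 (adjusted p 0.0449) with the coding length trend removed. PMP1 (0.22), PTK2 (0.19) and HRK1 (0.09) did not pass. Over samples left out, PTK2 ran from 0.117 to 0.254 and HRK1 from 0.004 to 0.166. The HSP30 call (adjusted p 0.0391) was lost without control replicate 1 (0.11), control replicate 2 (0.364) or manganese-adapted replicate 1 (0.109), and with no filter beyond a nonzero total (0.0772). The AST1 call was lost without the same samples (0.0588, 0.0513 and 0.202), in DESeq2 (0.0845) and with the coding length trend removed (0.0844). PTK2 passed with library size only (0.0437). PMP1 passed without control replicate 1 (log2 fold change 0.354). It also passed in limma with the crossed pairing (adjusted p 0.0295), with the GC trend removed (0.0398) and with the coding length trend removed (0.64, adjusted p 0.00016). In the CYSTM list, MNC1 rose and YDL012C fell by 0.29, while CPP1 (-0.19) and CPP3 (-0.03) did not pass. CPP1 passed with the GC trend removed (-0.44, adjusted p 0.000658) and with upper-quartile scaling (0.0485). CPP3 passed as higher with the coding length trend removed (0.38, adjusted p 0.00322). The YDL012C call was lost without manganese-adapted replicate 2 (adjusted p 0.114) and with the coding length trend removed (0.03, adjusted p 0.812). CPP2 had 0 reads in each library, a floor of 0.212 to 0.237 CPM. The median of this list (-0.11) and its mean (1.04) differ in sign. PMA2 and MNC1 are the genes the study of these samples is known for, so their lists are not independent of these samples.

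The phosphate list was not called (adjusted p 0.21): 15 members rose and 8 fell, with PHO89 (log2 fold change 3.31), PHM7 (1.94), PHO90 (1.00) and GIT1 (0.97) the largest.

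The iron regulon rose as a list: 27 of 30 members rose and 1 fell, with a median log2 fold change of 1.22 (camera adjusted p 4.8e-09). SIT1, a siderophore transporter, went from 37.4 ± 2.45 to 191 ± 4.94 CPM, FIT3 from 44.3 ± 3.96 to 220 ± 1.29, the iron oxidase FET3 from 55.5 ± 4.37 to 244 ± 22.4, and FIT2 from 54.7 ± 3.12 to 197 ± 4.91 CPM (SD, n = 2). The zinc list was called (adjusted p 0.046), with 7 of 15 members higher and 1 lower. ZRT1, the high-affinity zinc transporter, rose by 2.86 on the log2 scale, its regulator ZAP1 by 1.87 and ZPS1 by 1.57, and IZH2 fell by 1.23. That call was lost without manganese-adapted replicate 1 (adjusted p 0.0718), with the coding length trend removed (0.083), with the GC trend removed (0.0865), without overlapping genes (0.0527) and with camera on ranks (0.061). Its median was 0.21, and 0.26, 0.32, 0.19 and 0.21 under the first 4 of these. Both lists lost their call with an estimated correlation (camera adjusted p = 0.75 for each). That version rests on 2 residual degrees of freedom, and no list was called under it. The copper list was not called (adjusted p 0.33), with 7 of 11 higher and 3 lower. FRE7, a metal reductase, went from 39.2 ± 3.40 to 139 ± 1.78 CPM and COX17, a copper chaperone, from 188 ± 21.5 to 56.0 ± 5.71 CPM.

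Hexose transport, glyoxylate and gluconeogenesis, and peroxisomal beta-oxidation genes rose as lists. In hexose transport 17 of 23 rose and 4 fell (median 1.11, adjusted p 0.00076; median 0.43 with a pseudocount of 10 and 0.78 with the filter of 10 CPM), with HXT2, HXT13 (2.98), HXT10 (2.37) and HXT5 (1.96), a family whose close copies make single members uncertain. In the glyoxylate and gluconeogenesis list 15 of 22 rose and 2 fell (median 0.76, adjusted p 0.0018, and 0.49 with the coding length trend removed), with ADH2, ADY2 (2.59), ACS1 (2.54) and CRC1 (1.36). All 17 beta-oxidation members rose (median 1.24, adjusted p 6.4e-08), including POX1, DCI1, POT1 and PXA1. With an estimated correlation these calls were lost (adjusted p = 0.75 for hexose transport and beta-oxidation and 0.76 for glyoxylate and gluconeogenesis). The TCA list was not called (adjusted p 0.56), with 5 of 19 higher, among them CIT3 (2.09), and 4 lower. Nor was glycolysis (0.76), with 8 of 25 higher and 7 lower, among them ENO2 (-1.50). In trehalose and glycogen (0.82), 7 of 20 rose, led by PIG1 (1.27), and 9 fell, led by GSY2 (-1.11).

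Cytosolic ribosomal protein genes fell almost throughout: 137 of 138 fell, with a median log2 fold change of -1.33 (camera adjusted p 3.6e-28). RPS22A went from 1096 ± 295 to 209 ± 9.77 CPM (SD, n = 2), and RPL33A and RPL18B fell by 2.01 and 2.00. Each has a close copy and is uncertain. Between the control libraries, control replicate 1 lay nearer to the manganese-adapted libraries, with a median difference of -0.39 (control 1 minus control 2) over these genes and -0.19 over ribosome biogenesis. In that list 37 of 65 fell and 5 rose (adjusted p 0.00076), with NOP58 (-1.26) and NOP10 (-1.23) the lowest. Mitochondrial ribosomal protein genes fell in 65 of 71 and rose in 1 (median -0.64, adjusted p 1e-12), with MRP35 (-1.38) the lowest. With an estimated correlation, on 2 residual degrees of freedom, these calls were lost (camera adjusted p = 0.75, and 0.76 for ribosome biogenesis).

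Oxidative phosphorylation genes fell in 28 of 39 and rose in 2 (median -0.61, adjusted p 3.1e-05, and -0.35, adjusted p 0.017, with the coding length trend removed). ATP20 fell by 1.34 and COX12 by 1.13, while NDE2, an external NADH dehydrogenase, rose by 1.70. Antioxidant defence genes fell in 26 of 36 and rose in 4 (median -0.42, adjusted p 0.00076), with the thioredoxins TRX2 (-1.44) and TRX1 (-1.31) and the glutaredoxin GRX1 (-1.36) lower and the peroxisomal catalase CTA1 (1.56) higher. Proteasome genes fell in 17 of 33 and rose in 2 (median -0.26, adjusted p 0.0059), with PRE9 (-0.95) and PUP2 (-0.91) the lowest, and that call was lost without control replicate 2 (adjusted p 0.0771). With an estimated correlation these calls were lost (adjusted p = 0.75, and 0.76 for the proteasome).

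Genes of drug and multidrug efflux rose in 16 of 25 members and fell in 1 (adjusted p 0.00057), with PDR10 (2.33) and TPO2 (1.81) the highest, and the call was lost with the coding length trend removed (adjusted p 0.11, with 13 higher and 6 lower). Ergosterol synthesis was called (adjusted p 0.04), with 13 of 27 higher and 6 lower. UPC2, the regulator of sterol genes, rose by 2.06, ERG5 by 1.92 and ERG3 by 1.88. The ergosterol call was lost without manganese-adapted replicate 1 (adjusted p 0.0718), with the coding length trend removed (0.068) and with the GC trend removed (0.0958), and its median of 0.15 ran from 0.067 to 0.366 over samples left out. Meiosis and sporulation genes rose in 26 of 31 members and fell in 1 (median 0.70, adjusted p 5.5e-06, and 0.43 with a pseudocount of 10), with IME1, the early meiotic regulator, at 2.24 and SPS1 at 1.91. All 8 flocculation and adhesion genes rose (median 1.09, adjusted p 0.00021), with FLO11 at 2.47 and FLO10 at 2.34, in a family whose close copies make single members uncertain. With an estimated correlation these calls were lost (adjusted p = 0.75 for each).

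Among lists that were not called, stationary phase genes rose in 14 of 26 members and fell in 8 (adjusted p 0.10), with SNZ1 (3.10) and SNO1 (2.12) the highest. The list passed without control replicate 1 (adjusted p 0.0263), with the crossed pairing (0.0279) and with the coding length trend removed (0.0057). Heat shock genes went both ways (10 higher and 9 lower of 27, adjusted p 0.84), with BTN2 at 1.91 and SSA2 at -1.65. So did cell wall genes (23 higher and 18 lower of 46, adjusted p 0.56), where DAN1 rose by 3.03 and the median (0.33) and the mean (-0.02) differ in sign. Of the ER chaperone list 9 of 21 rose, KAR2 by 0.88, and 5 fell (adjusted p 0.45). Of the autophagy list 11 of 29 rose, ATG15 by 1.67, and 6 fell (adjusted p 0.45).

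In biosynthetic lists, 12 of 25 genes of arginine, lysine and histidine synthesis rose, ARG4 by 1.31, and 7 fell (adjusted p 0.33). In sulfur assimilation 9 of 28 rose and 10 fell, CYS3 by 1.36 (adjusted p 0.92, median 0.00, mean -0.02). In nitrogen catabolite repression 14 of 33 rose and 8 fell, the glutamine synthetase GLN1 by 1.58 (adjusted p 0.33). In purine synthesis 4 of 17 rose and 7 fell, IMD4 by 1.58 (adjusted p 0.68). Cell cycle and histone genes rose in 14 of 33 and fell in 10 (adjusted p 0.56), with the replication clamp POL30 at -2.23 and RNR1 at -1.82. Genes of a-cell mating rose in 9 of 18, FUS2 by 1.66, and fell in 4 (adjusted p 0.081, and 0.039 with the coding length trend removed). Counts adjusted over the list alone equalled those over all genes for every fixed list except glycolysis (7 higher and 7 lower), ER chaperones (10 and 5), cell wall (24 and 18) and autophagy (10 and 6).

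Markers of alpha cells were measured in this MATa strain. STE3 was at 5.92 ± 0.73 and 28.4 ± 2.50 CPM and rose, as did MF(ALPHA)1 (1.74) and SAG1 (0.91). MF(ALPHA)2 fell by 0.59. That call was lost without manganese-adapted replicate 1 (log2 fold change -0.32) and in DESeq2 (adjusted p 0.0629). It was also lost in limma with the coding length trend removed (-0.258, adjusted p 0.227). MATALPHA1 and HMLALPHA1 had 0 reads in every library. Reads of near-identical copies may not be counted, so this does not show that their RNA was absent. All 5 marker genes the labels list as deleted, ADE2, HIS3, LEU2, TRP1 and URA3, had reads in every library: URA3 was at 298 ± 19.7 and 138 ± 0.91 CPM, LEU2 at 470 ± 23.0 and 770 ± 85.4, ADE2 at 179 ± 11.8 and 128 ± 1.84, TRP1 at 50.9 ± 0.64 and 38.6 ± 2.08, and HIS3 at 38.5 ± 2.09 and 55.4 ± 1.70 CPM (SD, n = 2), control first. Alignments, which would show whether part of each gene remains, were not used here. That list was not called (adjusted p 0.65), and the TRP1 call (-0.39) was lost without manganese-adapted replicate 2 (adjusted p 0.051) and with the coding length trend removed (0.157). Mitochondrially encoded genes took 0.028% and 0.008% of reads in the controls and 0.026% and 0.055% in the manganese-adapted libraries. Of 6 tested, 3 rose, and the list was not called (adjusted p 0.18) but passed without control replicate 1 (adjusted p 0.000257) and with the crossed pairing (0.00863). COX3 (1.89) and COX2 (1.51) passed in limma but not in edgeR's quasi-likelihood test (adjusted p 0.262 and 0.389) or DESeq2 (0.124 and 0.298). Neither call held without manganese-adapted replicate 2, where log2 fold changes were 1.287 and 1.04. COX2 was also lost without manganese-adapted replicate 1 (1.985). Its groups overlapped, with 26.68 CPM in control replicate 1 and 26.55 in manganese-adapted replicate 1.

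**Figure D2:**
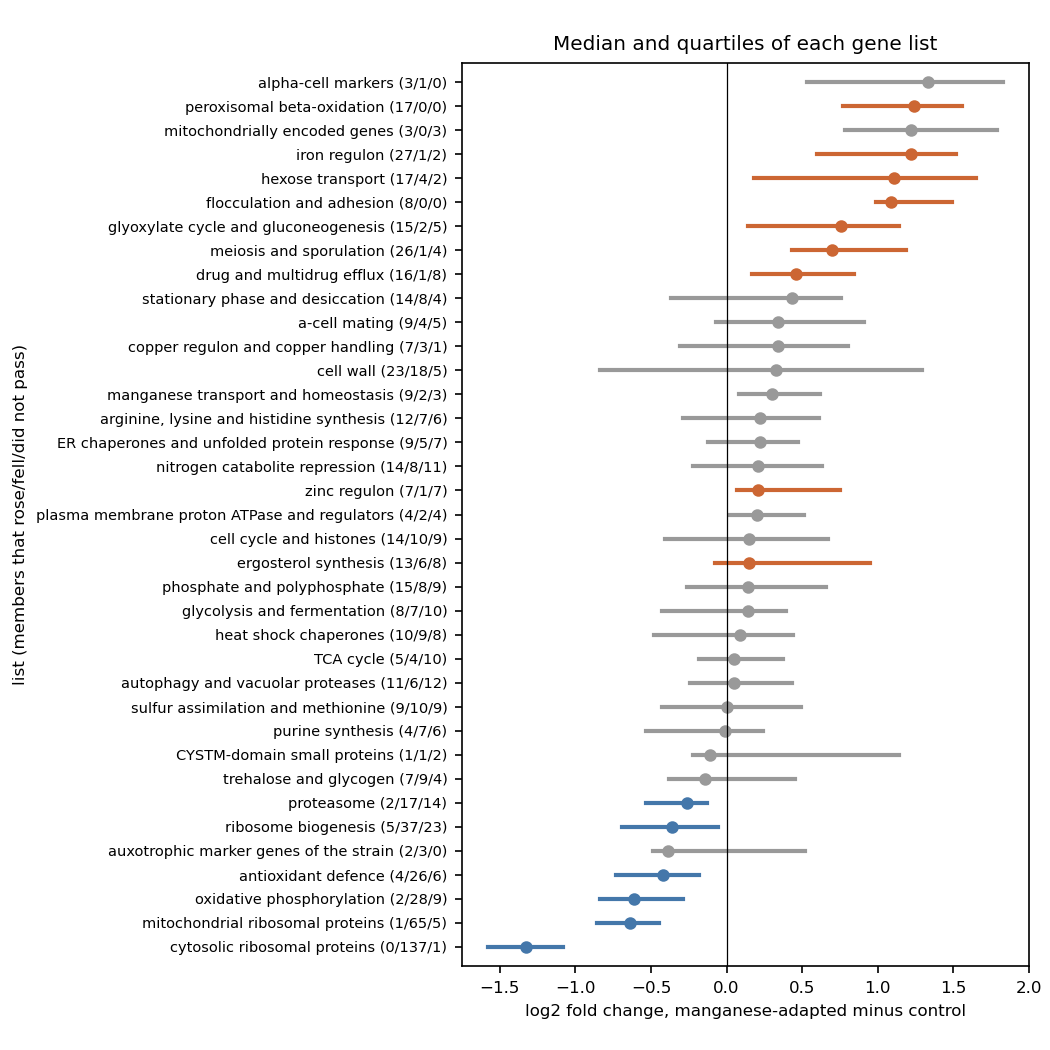
Median (points) and quartiles (bars) of log2 fold change, manganese-adapted minus control, for each of the 37 lists, with counts of members that rose, fell or did not pass. Orange and blue mark lists called by camera at the preset correlation as higher or lower, and grey the others; cytosolic ribosomal proteins have the lowest median, -1.33.

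In the authors' deposited table, 4217 features had a false discovery rate under 0.05, and 4166 of the 4188 of these that were tested here were also called by limma with the same sign. On the recovered reads, edgeR's quasi-likelihood test called 4329 genes. Groups were separated in 85.7% of tested genes, where chance gives 33.3% for 2 against 2. Fold changes trended with coding length (Spearman's rho 0.38 across 5777 genes), from a median of -0.58 at up to 300 bp to 0.33 above 3000 bp. With that trend removed, 3928 of 5777 genes changed, 1724 higher and 2204 lower, and 732 at least 2-fold (452 higher, 280 lower). Of these 3928 calls, 3205 were shared with the main test in the same direction.

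**Figure D3:**
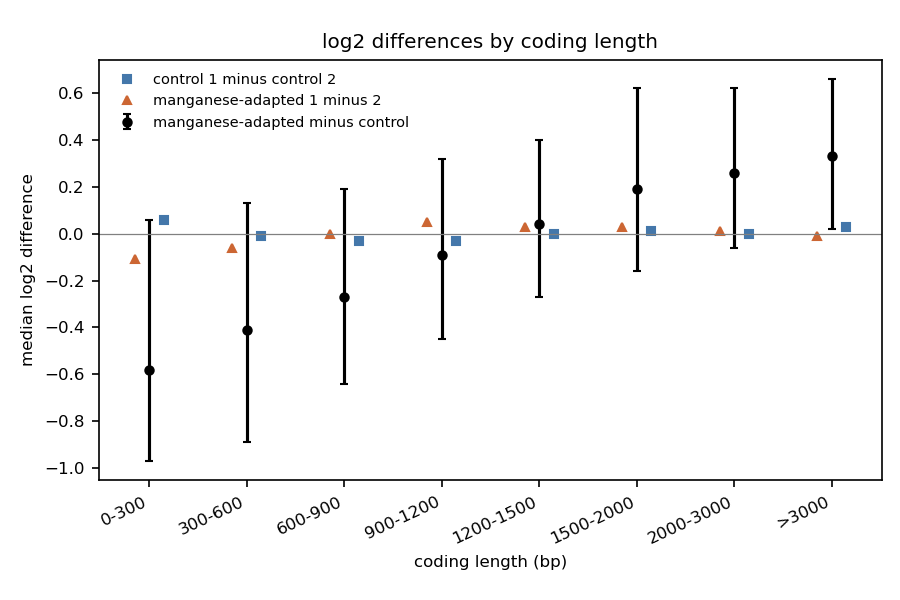
Median log2 difference by coding length (bp) for manganese-adapted minus control (black, bars are quartiles) and for the differences between replicates (blue squares for control, orange triangles for manganese-adapted). The group difference runs from -0.58 to 0.33, while the replicate differences lie between -0.11 and 0.06.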

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

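The quasi-likelihood test, crossed pairing, trend removals, overlap filter and fry with the replicate block were chosen after the data were seen. Over 21 alternatives, genes changed numbered 3316 to 4426. Genes changed at least 2-fold numbered 625 to 1119, and the 625 came with a pseudocount of 10, which shrinks low genes by construction. Without 1 sample at a time (a lone sample is assumed to vary like the other group), the counts ran from 3316 to 4279, from 885 to 1119 and, for called lists, from 13 to 17. Lists called by camera fell from 15 to 0 with an estimated correlation. Fry called 19 lists, and 0 with the replicate block. Without the block it did not call ribosome biogenesis (fry adjusted p 0.068) or the proteasome (0.052), which camera had called. The cause was not tested for either fall, and both rest on few residual degrees of freedom. Camera with an estimated correlation used 2, and the block left fry fewer still. With the block, fry's adjusted p was at least 0.088 for every list. Neither fall therefore decides against a list. Lists with low estimated correlations also lost their call, such as flocculation (0.022) and drug efflux (0.04), with camera adjusted p 0.75 for each. A high correlation between members was therefore not needed for the loss. Of the 15, 11 kept direction and call in every other camera alternative; zinc, ergosterol, proteasome and drug efflux did not. Of 177 named genes, 166 were tested under every alternative, and 149 of these kept direction and call.

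With the replicate block, 4196 genes changed, 975 at least 2-fold, and 15 lists were called; BSD2 was the only named gene whose call it ended. Same-numbered samples deviated in opposite directions (correlation -0.179), so the numbers were not taken to pair samples. The crossed pairing, which no label gives, yielded 4426 genes, 975 at least 2-fold and 17 lists. With 2 samples per group its correlation (0.179) mirrors that of same-numbered samples by construction. Calls gained under it are therefore not independent support.

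Directions turned as follows; the cause was not tested. With the coding length trend removed, log2 fold changes were -0.085 for YPK9, -0.082 for SMF1, -0.124 for PTK2, -0.216 for HRK1, 0.026 for YDL012C, 0.136 for CPP1 and 0.376 for CPP3 (adjusted p 0.00322); MTM1 was -0.036 with GC removed, and CPP3 0.141 without manganese-adapted replicate 1 (-0.197 without replicate 2). PMA1, at 0.00, was 0.004 with RLE factors, 0.022 with library size only, 0.009 in DESeq2, 0.006 in both edgeR tests, 0.001 without mitochondrially encoded genes, and 0.077 and 0.120 without control replicate 1 and manganese-adapted replicate 2 (from -0.121 without manganese-adapted replicate 1). Camera's direction turned for 4 lists that were not called, with medians as follows: heat shock 0.006 (without control replicate 1, up to 0.171 without another), 0.088 (crossed) and -0.087 (length); glycolysis 0.012 and 0.093 (without control replicate 1, without manganese-adapted replicate 1; up to 0.212) and -0.016 (GC); cell wall 0.301 and 0.330 (without control replicate 1, 2; 0.224 to 0.356 over samples left out) and 0.326 (crossed), where median and test differ in sign; sulfur -0.098 (without control replicate 1, up to 0.140), -0.004 (crossed), -0.127 (length) and -0.018 (GC). Depth limits genes near 0.212 to 0.237 CPM, the value of 3 reads.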

Other observations

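Tests on the coding length trend and on control replicate 1 were chosen only after the result was seen; those on calcineurin targets, inositol genes and chromosome ends were written before it was. The gene lists in this part were chosen after the data were seen.

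Targets of calcineurin and its transcription factor Crz1, which respond to calcium and cell wall stress, rose in all 15 of 15 tested members (median log2 fold change 1.56; 7 of 16 members are also in the lists above), and 13 rose with the coding length trend removed. CMK2 went from 242 ± 5.18 to 1751 ± 4.56 CPM and PMC1, the vacuolar calcium pump, from 324 ± 29.4 to 1094 ± 0.99 CPM (SD, n = 2). As a hypothesis, calcineurin activity may be higher in the adapted cells: of 7 targets not looked at before, 6 were tested, all 6 rose, and their median was 1.08, above the 0.5 set beforehand. ENA1 and ENA5 among them may share reads with close copies, which was not tested. Transcripts of the pathway itself moved less, CRZ1 by 0.41 (0.13, adjusted p 0.173, with the coding length trend removed), CNA1 by 0.74 and CNB1 by -0.68. With the trend removed CNA1 was at 0.521 and CNB1 at -0.405. CMP2 did not pass (-0.095, and -0.346, adjusted p 0.00329, with the trend removed). Culture time is not excluded.

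INO1 may stand for a release of the inositol-responsive genes. The list used to test this holds genes of inositol and phospholipid synthesis, not all of which need respond to inositol. Of 16 other tested members of that list 8 rose and 4 fell, and the median was 0.24, between the bounds of 0.5 and 0.2 set beforehand, so the test did not decide. With the coding length trend removed 7 rose and 6 fell and the median was 0.07, under the lower bound, over members that still went both ways. ITR1 (2.03), OPI1 (1.68) and INO2 (1.48) rose and PIS1 fell by 1.31. Genes within 30 kb of a chromosome end may rise as a class: outside the fixed lists, 249 such genes had a median of 0.36 (126 rose, 55 fell), above all 10000 random lists matched on mean expression (median of the random medians 0.04), and 0.39 with the coding length trend removed. Many of these genes belong to families with close copies, which leaves reads shared between copies open.

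Short genes were lower and long genes higher in the manganese-adapted libraries. The short genes of the fixed lists are not the whole cause, since rho was 0.35 (bootstrap SD 0.014) among 4760 genes outside them. The trend was weaker between replicates (largest rho 0.12) than in the 4 between-group pairs (at least 0.35). With 2 libraries per group, and pairs that share libraries, this cannot decide on library-to-library differences in fragment recovery. RNA or library quality shared by both libraries of a group cannot be told apart from a difference between the groups, since all 4 pairs gave a rho of 0.35 to 0.39 and quality is confounded with group. The trend is not the whole cause of 12 of 15 list calls, which stayed called in the same direction with it removed; for the other 3, medians (quartiles) went from 0.21 (0.07 to 0.75) to 0.32 (-0.06 to 0.57) in zinc, from 0.15 (-0.08 to 0.95) to 0.13 (-0.18 to 0.71) in ergosterol and from 0.46 (0.17 to 0.84) to 0.24 (-0.20 to 0.60) in drug efflux, adjusted p 0.083, 0.068 and 0.11, and the trend's part in these 3 cannot be told apart.

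Control replicate 1 lay nearer to the manganese-adapted libraries than control replicate 2. Noise in control replicate 2 alone predicts no positive relation, but the rho between the manganese-adapted mean minus control 1 and control 1 minus control 2 was 0.26 (bootstrap SD 0.012). The coding length trend is argued against by a rho of 0.06 with length, against 0.38 for the group difference. Reads of manganese-adapted cells mixed into control replicate 1 would give equal shares, but the median implied share was 17.3% from genes at least 2-fold lower and 3.5% from genes at least 2-fold higher (SD of the difference 1.42). A difference in growth stage between the control samples stays open as an untested hypothesis.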
